A study of Mus musculus with 12 samples.

How the data were processed

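Unsorted cells and nuclei of mouse skin were profiled by droplet single-cell RNA sequencing (10x Genomics 3' chemistry) and by single-cell ATAC sequencing, which counts insertions of a transposase in open chromatin. Per the labels, the 12 libraries fall into 6 groups in each assay: unwounded skin of the face and of the back (dorsum), and wounds of either site treated with PBS or with an inhibitor of EP300, a histone acetyltransferase. The protocol describes skin of 6 mice pooled for each condition and wounds at postoperative day 14, in its passage on nuclei; elsewhere it also names an earlier day, so the day of the RNA libraries rests on that passage. Each group held 1 library per assay. The protocol mentions hashtag oligonucleotides, but all 10 hashtag features held 0 UMIs in each RNA library, so single mice could not be separated.

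The deposited RNA matrices hold counts of unique molecular identifiers (UMIs) per gene and barcode, which the authors made with Cell Ranger 6.1.2 per the file headers, against a combined human and mouse gene set. The deposited ATAC matrices hold insertion counts per peak and nucleus, with 1 peak set per library, made with Cell Ranger ATAC 2.1.0 per the file headers. A further deposited matrix holds counts of insertions summed over the peaks that carry each transcription factor motif. The submitters' notes name Seurat 3.1.1 and a human genome build, and do not state what Seurat was used for. No normalization by the authors was found in the values, which were whole numbers. The build of the peaks is not named in the files; peaks were compared with mouse RefSeq genes of the GRCm38 assembly, where 53.4% to 64.4% of genes had a peak at an end, against 8.01% to 19.9% after a shift of 1 Mb.

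Only mouse genes were used. Barcodes with 300 or more genes and 20% or fewer mitochondrial UMIs were kept, and doublets called by the Scrublet method in scanpy 1.11.5 were removed. This automatic caller has not worked in 5 of the libraries, where it called 0 to 2 doublets (under 0.5% of cells); in the dorsal PBS wound it called 1006. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes and 30 principal components were taken, and cells of the 6 libraries were clustered together by the Leiden method (igraph 0.11.9, 15 neighbours, resolution 1.0). A cluster was named after 1 of 16 cell classes from fixed marker lists when at least 3 markers of the class were each found in 20% or more of its cells and 1.5-fold or more above the other cells; clusters that did not meet this, that held more markers of another class among their 10 leading genes, or that were shallow with no marker among them, stayed unnamed. Cells of the 3 fibroblast-like clusters (numbers 7, 17 and 29) were called fibroblast-like. Their leading genes, which define them, are for cluster 7 Gpc3, Tnmd, Hpgd, Slit2, Dpep1, Ogn, Cyp1b1, Cdkn1c, Peg3 and Igfbp4, for cluster 17 Pcolce2, Scara5, Cdh4, Cpz, Osr2, Efemp1, Col1a2, Cyp26b1, Dcn and Col1a1, and for cluster 29 Cxcl5, Mmp3, Sfrp2, Tnc, H19, Saa3, Prg4, Cthrc1, Gpx3 and Prss35.

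For each of 6 contrasts between 2 libraries, UMIs were summed over fibroblast-like cells and scaled to CPM (counts scaled to a total of 1e6) over non-mitochondrial genes. A log2 ratio with a pseudocount of 5 CPM was taken for each gene with 20 or more UMIs over both libraries. Exact Poisson intervals of CPM, an exact binomial interval of each ratio (without the pseudocount) and Clopper-Pearson intervals of shares are at the 95% level and cover counting error only. A gene with no UMI in 1 library is given as a bound against a floor of 3 UMIs in that library. With 1 library per group there is no test, p-value or standard error. For 21 gene lists, the median log2 ratio of measured members was set against 10000 random lists of the same size drawn from 20 bins of expression, and given as a percentile; its interval comes from 500 draws of the counts. Members 1.5-fold or more higher or lower were counted. The matrix list shares 5 members with the fibroblast markers (Col1a1, Col1a2, Col3a1, Col5a1 and Fbn1), and the papillary and WNT lists share 3 members. Size factors by the median of ratios gave the shift by which total-count scaling moves all genes of a contrast. Gene ratios are given as scaled by total counts.

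The genes named per contrast followed a rule: the 8 highest and 8 lowest ratios among genes with 50 or more UMIs over both libraries, found in 5% or more of fibroblast-like cells of the higher library and there at 20% or more of the CPM of the class with the most, without mitochondrial, ribosomal, haemoglobin, immunoglobulin, sex-linked marker and predicted genes; up to 4 members per list; and Robo2, Eid1 and Ep300 throughout. The contrasts, lists, cell markers, motif families, the rule for naming genes and most alternatives were fixed before the data were examined. All 8 highest, 8 lowest and 3 fixed genes of each contrast are named. The lists and list members given for each contrast were picked from those the rule allows after their values and their reversals under alternatives were seen, which was not planned, and each list is given in at least 1 contrast. Only results called as different could be counted as turned. Of those given, 41 of 194 called gene ratios and 21 of 42 called list medians turned direction under at least 1 alternative; of those left out, 83 of 254 and 6 of 15 did, so the gene ratios given turned less often than those left out. The cell cycle list of the facial PBS wound was first left out because it turned, and was put back.

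ATAC nuclei were clustered in each library by latent semantic indexing on the 25000 most frequent peaks, and named from peaks within 2000 bp of marker genes. Peaks were called shared when they overlapped by 1 bp or more (bedtools 2.31.1), and insertion counts near genes were compared over regions open in both libraries. For 18 motif families, and for motifs with 1000 or more counts, the share of all motif counts in fibroblast-like nuclei was compared.

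The procedure was tested on simulated data in which 50 genes per fold were altered in libraries of the real depth. In the dorsal over facial contrast of unwounded skin, 78% of genes altered 2-fold and 94% altered 3-fold were called among 11496 genes, and in the dorsal over facial contrast of PBS wounds 62% and 80% among 13684. In the other 4 contrasts, with 12470, 13213, 12339 and 13147 genes, 70% to 82% of the genes altered 2-fold were called, and in the dorsal inhibitor contrast 72% of those altered 3-fold. Of genes altered 1.5-fold, 6% (dorsal inhibitor contrast) to 24% (facial inhibitor contrast) were called, so a gene that lies between may well differ by that much. Of unaltered genes, at most 0.321% were called. Of 100 lists of 15 unaltered genes per contrast, 5% or 6% lay outside the central 95% of random lists. Both simulated libraries were drawn from the same pooled profile with counting error alone, and the genes varied independently. These rates thus leave out differences between libraries, mice and cluster mixes, and genes of a list that vary together.

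Alternatives covered the cell filter, doublets, clustering per library, the weight of each cell, depth, scaling, the pseudocount, the UMI minimum, peak overlap, the number of peaks, and the choice and weight of nuclei. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0. UMIs assigned to human genes, barcodes outside the filter and unnamed clusters were left out of the contrasts, because they could not be assigned to a mouse cell class.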

Results

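Single cells and single nuclei of mouse skin were measured in 6 groups: unwounded face, facial wounds with PBS, facial wounds with an EP300 inhibitor, unwounded dorsum, dorsal wounds with PBS and dorsal wounds with the inhibitor. The series asks how the site of origin of skin fibroblasts relates to scarring. Each group held 1 RNA library and 1 ATAC library, so no spread between replicates exists; values are described as higher or lower, without a test, and intervals cover counting error only. The RNA libraries held 45565279, 51293719, 27131193, 43905516, 75502585 and 33955884 mouse UMIs in the order of the groups above. After filtering, 6481, 4758, 4512, 4471, 16619 and 2345 cells remained. The ATAC libraries held 2004, 3784, 6762, 7469, 3290 and 5366 nuclei with 26541534 to 133845317 insertions in peaks. Both dorsal wound libraries are named in a different series from the other 4 libraries of each assay, so a preparation batch and the dorsal wound cannot be told apart.

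Fibroblast-like cells, the collagen-producing cells of the dermis, made up 8.87% of cells in unwounded face (95% interval 8.19 to 9.59) and 16.9% in unwounded dorsum (15.8 to 18.0). Their share was 23.2% in the facial PBS wound (22.0 to 24.4) and 10.4% in the facial inhibitor wound (9.54 to 11.3). In the dorsum it was 8.61% in the PBS wound (8.19 to 9.05) and 19.4% in the inhibitor wound (17.9 to 21.1). These shares moved with the method. With more doublets removed they were 5.63% in unwounded face and 6.48% in the facial inhibitor wound. There a cluster of 796 cells led by Coch, with 6 fibroblast markers, stayed unnamed and held 166 and 122 cells of these libraries. With each library clustered by itself the share was 12.3% in the dorsal inhibitor wound. There clusters of 83 and 85 cells with fibroblast as best class stayed unnamed. These falls may thus rest on the naming rule. Among ATAC nuclei the share was 23.8% in unwounded face and 13.6% in unwounded dorsum, where another random start of the clustering called 1760 in place of 1019 of 7469 nuclei. In the facial wounds it was 11.7% with PBS and 14.9% with the inhibitor, or 14.4% and 13.5% without shared or low-count barcodes. The dorsal wounds had 18.3% and 18.2%. The order of these groups thus rests on the assay and the method, and no difference in the share of fibroblasts is read from it. Immune-like cells made up 74.7% of RNA cells in the dorsal PBS wound, against 9.26% in unwounded dorsum, 36.9% in the dorsal inhibitor wound and 12.1% in the facial PBS wound. Neutrophil-like cells, marked by S100a8 and S100a9, made up 30.5% there (29.8 to 31.2), 6.52% in the dorsal inhibitor wound (5.56 to 7.60) and 0.483% in the facial PBS wound. Nuclei of the dorsal wounds did not share this difference: with PBS 13.6% were neutrophil-like, 17.4% monocyte- and macrophage-like and 11.1% T- and NK-like, and with the inhibitor 14.4%, 17.7% and 12.7%. Monocyte- and macrophage-like cells numbered 3151 in the dorsal PBS wound and were 11.3% of the dorsal inhibitor wound, 3.53% of the facial PBS wound and 0.820% of the facial inhibitor wound. Taken over non-immune cells alone, the fibroblast-like share was 34.1% in the dorsal PBS wound and 30.8% in the dorsal inhibitor wound; over mesenchymal and endothelial cells it was 40.6% and 52.4%, the other way round. Cells in unnamed clusters were 65.5% of unwounded face and 1.72% of the dorsal PBS wound, so shares of all cells are not like for like between libraries. Fibroblast-like cells fell into 3 clusters: cluster 29 held 95.7% of those of the dorsal PBS wound, 38.2% of the dorsal inhibitor wound, 10.4% of the facial PBS wound and at most 4.26% of the other libraries. Cluster 17 held 74.5% of those of unwounded dorsum and 0.210% of the dorsal PBS wound. A cluster made mostly of 1 library may differ by that library alone. The depth of fibroblast-like cells ranged from a median of 5300.5 UMIs per cell in the facial inhibitor wound to 16032.5 in the dorsal inhibitor wound, and their sums from 2540344 to 12024278 UMIs.

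**Figure D1:**
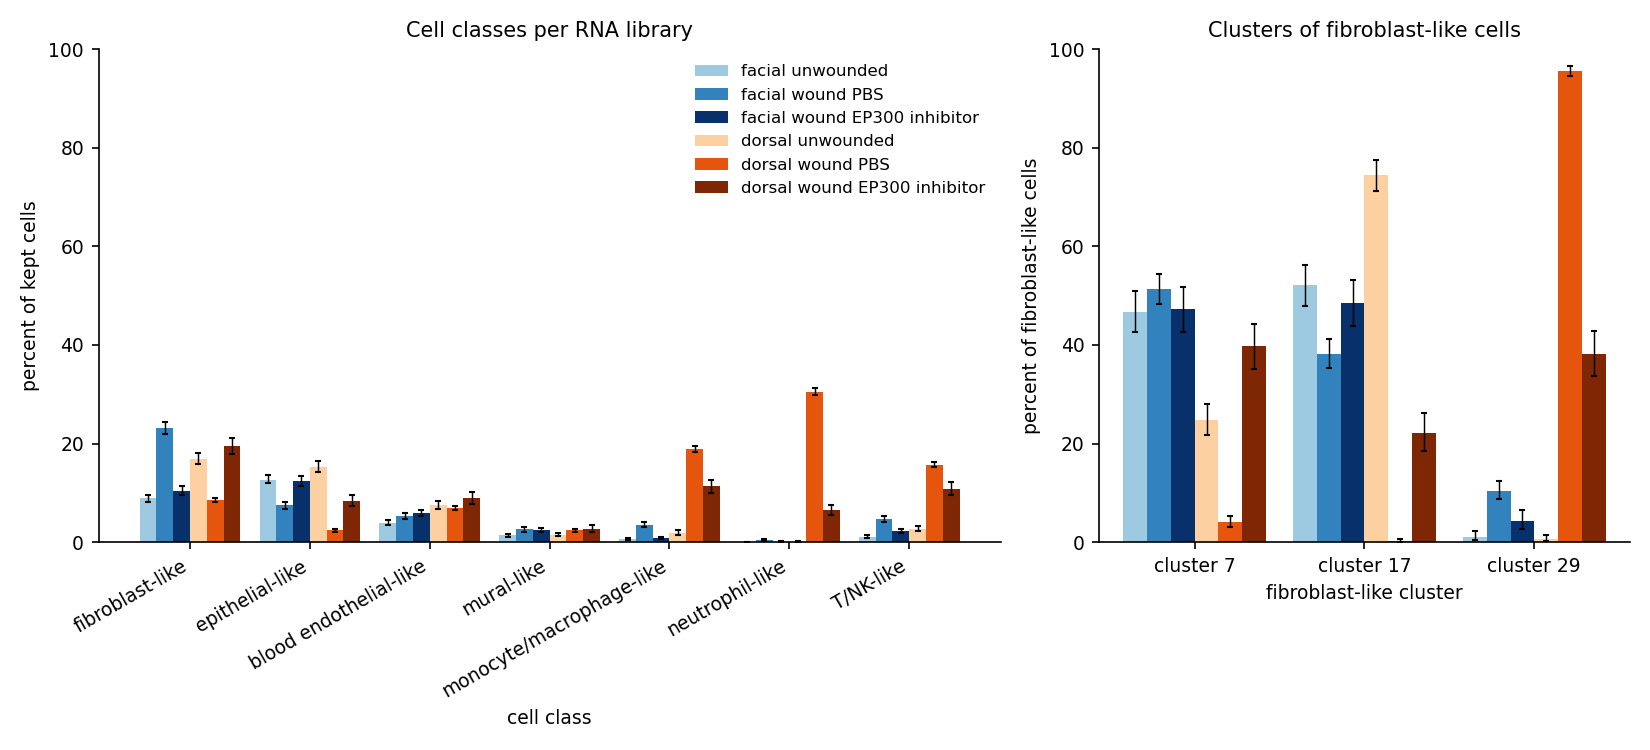
Share of cells per class in each RNA library (left, percent of kept cells) and share of fibroblast-like cells in clusters 7, 17 and 29 (right, percent); bars are single libraries and lines 95% binomial intervals. Neutrophil-like cells reach 30.5% and cluster 29 reaches 95.7% in the dorsal PBS wound.

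Unwounded dorsum was compared with unwounded face to describe fibroblast-like cells of both sites before injury. Each site is 1 library, and cluster 7 held 24.9% of these cells in dorsum against 46.8% in face, cluster 17 74.5% against 52.2%, so site, library and cluster mix are not separated. Dorsal fibroblast-like cells had more HOX transcripts, the genes that mark position along the trunk: Hoxc8 had 187 UMIs in dorsum and 1 in face (log2 ratio 2.57; interval of the ratio itself 3.84 to 11.64), and Hoxc6 a log2 ratio of 2.27. Of 10 cranial mesenchyme regulators, 5 were higher in facial cells: Tfap2b, a neural crest transcription factor, had a log2 ratio of -2.12, and Pax3, another one, was at least 18.6-fold lower in dorsum, where it had 0 UMIs. Contractile genes were lower in dorsum, with Acta2, the smooth muscle actin of myofibroblasts, at -1.50. Immediate early genes, which respond to stress and tissue dissociation, were higher in dorsum, with Atf3 at 1.47.

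Of 15 measured HOX genes, 11 were 1.5-fold or more higher in dorsum, 1 was lower and 3 lay between, with a list median of 0.94 (1.1005 with the 2 genes at 0 in 1 library set to their bound; percentile 100 of random lists). Hoxc4 (2.06) and Hoxb3 (1.67, 1 UMI in face, interval of the ratio 2.66 to 10.50) were among them. Of 10 cranial regulators, 5 were lower, 5 between and none higher (median -0.70), including Foxd1 (-1.20). The trunk dermis regulators had 4 of 7 members lower and 1 higher (median -0.69). The contractile list had 11 of 14 members lower and 3 between (median -0.72), with Lrrc15, a marker of wound and tumour myofibroblasts, at -1.58, Tpm2 at -1.17 and Tagln at -1.13. Immediate early genes had 11 of 17 members higher and 6 between (median 0.74), with the phosphatase Dusp1 at 1.38. The lower median of this list in the dorsal PBS wound, given below, uses the same unwounded dorsum library. The matrix list had 5 of 24 members higher, 6 lower and 13 between (median -0.01, percentile 28.7). Within it Col1a2, the second chain of type I collagen, which is also a fibroblast class marker and leads cluster 17, was at 1.07. Postn, a matrix protein of healing tissue, was at -1.48, Tnc, which leads cluster 29, at -1.61 and Col12a1 at -1.57. Papillary genes had 4 of 12 members lower and 8 between (median -0.45), and matrix proteases 2 of 17 higher, 2 lower and 13 between (median 0.26, percentile 99.6).

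Among genes that passed the naming rule, which Tfap2b did not, the highest in dorsum were Mup20, a major urinary protein (at least 52.5-fold higher, 0 UMIs in face), the cytokine Il6 (log2 ratio 3.13, 434 UMIs against 8), Wfdc12 (3.07), the transcription factor Sox11 (2.48), Pi15 (2.46) and Cyr61, a target of mechanical signalling (2.40). Lowest of them were Myoc (-3.23), Mgp, an inhibitor of calcification (-3.15), the WNT modulator Sfrp2 (-2.58), which leads cluster 29, Cilp (-2.42), the chemokine Cxcl14 (-2.31), Cygb (-2.25), the complement component C3 (-2.14) and Igfbp4 (-1.99), which leads cluster 7. None of the 7 measured SLIT/ROBO genes, which guide axons and migrating cells, differed 1.5-fold (median -0.20), with Slit3 at -0.58 and Robo2 at 0.17 (70.8 against 62.2 CPM; interval of the ratio -0.06 to 0.44). EP300 and its partners lay between throughout (13 of 13 members, median -0.07), with Ep300 at 0.04 and Eid1, an inhibitor of EP300, at -0.15. Scaling shifted all genes of this contrast by -0.10; relative to that shift the medians were 1.04 for HOX, -0.60 for cranial, -0.59 for trunk, -0.62 for contractile, 0.84 for immediate early, 0.09 for matrix, -0.35 for papillary, 0.36 for proteases, -0.10 for SLIT/ROBO and 0.03 for EP300 genes. Directions turned in cluster 7 alone for papillary genes (0.03), proteases (-0.28), Pi15 (-0.38) and Postn (0.14), with more doublets removed for Acta2 (0.19), and with cells thinned to 1000 UMIs for the trunk list (0.42). The matrix median ran from -0.10 with more doublets removed to 0.19 with thinned cells.

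The facial PBS wound was compared with unwounded face to describe healing in facial skin. Inflammatory genes were higher in wound fibroblast-like cells: Saa3, an acute-phase protein that leads cluster 29, had a log2 ratio of 4.75 (1981 UMIs against 4), and the monocyte chemokine Ccl2 had 1.77. Contractile genes were also higher, with Lrrc15 at 1.09. Most matrix genes lay between; among the 6 of 24 that were higher were Postn at 1.26 and Cthrc1, which leads cluster 29, at 1.82. Cluster 29 held 10.4% of fibroblast-like cells in the wound and 1.04% in unwounded face, and immune-like cells were 12.1% against 3.87% of all cells.

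Inflammatory genes were 1.5-fold or more higher in 11 of 18 measured members and between in 7 (median 0.75; 0.92 with the 2 genes at 0 at their bound; percentile 100), including Cxcl1 (1.51), which attracts neutrophils. Among contractile genes 8 of 14 were higher and 6 between (median 0.59), with Tpm2 at 1.06 and Acta2 at 0.75. Matrix genes were higher in 6 of 24, lower in 1 and between in 17 (median 0.38, percentile 99.6), with Tnc at 1.21, again a leading gene of cluster 29, and Col6a3 at 1.03. Interferon-stimulated genes were higher in 4 of 12 and between in 8 (median 0.36), with Ifi27l2a at 1.46 and Bst2 at 1.01. Cell cycle genes were higher in 2 of 17 and between in 15 (median 0.27); this median turned to -0.09 with a stricter cell filter, -0.16 with called doublets kept, -0.45 with each library clustered by itself and -0.25 with each cell weighing the same. All 15 measured YAP/TEAD genes (median 0.08, percentile 51.6) and all 7 SLIT/ROBO genes (median 0.04, percentile 38.4) lay between. Among genes that passed the naming rule, which Saa3 did not in this contrast, the highest were Prss35, which leads cluster 29 (2.56), the B-cell chemokine Cxcl13 (2.07), Steap4 (1.92), Igfbp3 (1.82), the fibrillin Fbn2 (1.79) and the metalloprotease Adam12 (1.79). Lowest of these were Scg3 (-1.48), Myoc (-1.44), Spon2 (-1.43), the basement membrane collagen Col4a5 (-1.39), Ptpre (-1.31), C7 (-1.29), Thbs4 (-1.29) and Haus8 (-1.26). Robo2 was at 0.48 (88.9 against 62.2 CPM), Eid1 at 0.20 and Ep300 at 0.07. With the facial inhibitor wound in place of the PBS wound the contractile median was -0.36 and the inflammatory median -0.21, and Acta2 (-1.60), Tpm2 (-0.83), Lrrc15 (-0.43), Tnc (-0.16), Ccl2 (-0.51), Cxcl1 (-0.06) and Myoc (0.10) turned, while the matrix median was 0.17.

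The dorsal PBS wound was compared with unwounded dorsum to describe healing in skin of the back. Its fibroblast-like cells had far more inflammatory, matrix-remodelling and contractile transcripts: Saa3 had a log2 ratio of 11.18, the neutrophil chemokine Cxcl5 was at least 2449-fold higher (0 UMIs in unwounded dorsum; 11169 in the wound), and Tnc, a matrix protein of wounds, had 7.21. All 3 lead cluster 29, which held 95.7% of the wound's fibroblast-like cells and 0.661% of those of unwounded dorsum, so these values and those of clusters 7 and 17 describe a contrast between clusters. Lower were Pcolce2 (-4.35), Scara5 (-3.57) and Cdh4 (-4.38), which lead cluster 17, a cluster with 0.210% of the wound's fibroblast-like cells. Immune-like cells were 74.7% against 9.26% of all cells, and S100a8 with S100a9 reached 2631 CPM in the wound's fibroblast-like cells, a possible sign of free neutrophil RNA.

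Inflammatory genes were higher in 13 of 18 members, lower in 4 and between in 1 (median 3.35, percentile 100), with Lcn2 at 7.03 (1 UMI in unwounded dorsum, interval of the ratio 9.72 to 17.50) and Cxcl2 at 6.83 (3 UMIs, interval 8.93 to 12.76). Contractile genes were higher in 14 of 15 and between in 1 (median 1.91; 1.93 with 1 gene at its bound), with the actin crosslinker Actn1 at 3.26, Lrrc15 at 2.95 and Tpm2 at 2.55. Interferon genes were higher in 10 of 12, lower in 1 and between in 1 (median 1.42), with Ifi27l2a at 3.48. Genes of hypoxia and glycolysis were higher in 11 of 16 and between in 5 (median 1.12), with pyruvate kinase Pkm at 1.76, Pgk1 at 1.53 and the glucose transporter Slc2a1 at 1.83. Matrix genes were higher in 17 of 24, lower in 3 and between in 4 (median 0.81), with Col12a1 at 5.43, Postn at 3.91 and Cthrc1, which leads cluster 29, at 2.84. TGF-beta pathway genes were higher in 10 of 18, lower in 3 and between in 5 (median 0.66), with Pmepa1, a feedback inhibitor, at 2.88 and Ltbp1, which binds latent TGF-beta, at -2.94. Cell cycle genes were higher in 10 of 17 and between in 7 (median 0.71). Immediate early genes were lower in 9 of 17 and between in 8 (median -0.61), with Fos at -1.67 and Klf4 at -1.48. The median of this list was 0.74 in unwounded dorsum over face. It was -0.04 in the facial PBS wound over unwounded face and 0.26 in the dorsal over the facial PBS wound. Both 0.74 and -0.61 use the unwounded dorsum library, so a deviation of this library alone would give both. Papillary genes were lower in 6 of 11, higher in 2 and between in 3 (median -0.70), with the WNT enhancer Rspo1 at -3.22 and the retinoic acid binder Crabp1 at 2.60. SLIT/ROBO genes were lower in 4 of 7 and between in 3 (median -0.65), with Robo1 at -1.54 and Robo2 at -0.79 (38.9 against 70.8 CPM; interval of the ratio -1.06 to -0.67).

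Under the naming rule, which Lcn2 and Cxcl2 did not pass, further genes at the upper end were the collagenase Mmp13 (at least 813-fold higher), the imprinted RNA H19 (at least 643-fold higher), Sfrp2 (6.16) and the lubricin gene Prg4 (5.88), of which the last 3 lead cluster 29, and Plac8 (5.45). At the lower end stood Gpha2 (at least 305-fold lower, 0 UMIs in the wound), the aldehyde dehydrogenase Aldh3a1 (-4.74), Ppp1r14a (-4.54), Igfbp2 (-4.25) and the phospholipase Pla2g5 (-3.57). Eid1 was at -0.07 and Ep300 at 0.20. Scaling shifted all genes by 0.27; relative to it the medians were 3.08 for inflammatory, 1.64 for contractile, 1.15 for interferon, 0.85 for hypoxia, 0.54 for matrix, 0.38 for TGF-beta, 0.43 for cell cycle, -0.98 for papillary, -0.89 for immediate early and -0.92 for SLIT/ROBO genes. In cluster 7 alone, of which the wound library held 59 cells, the inflammatory (-0.66), TGF-beta (-0.08), cell cycle (-0.88), papillary (0.73) and SLIT/ROBO (0.19) medians turned, as did Scara5 (0.58), Robo2 (0.76), Cthrc1 (-0.01), Ltbp1 (0.51) and Rspo1 (0.09), while the matrix median was 0.73. With the dorsal inhibitor wound in place of the PBS wound the SLIT/ROBO median was 0.02 and Klf4 0.03.

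The PBS wounds of dorsum and face were compared because the study sets scarring at these sites against each other. Fibroblast-like cells of the dorsal wound had more inflammatory and matrix transcripts: Saa3 had a log2 ratio of 7.17, Cxcl5 of 6.94 and the iron-binding protein Lcn2 of 6.35, while the matrix proteins Tnc and Col12a1 had 4.39 and 3.04. The HOX difference of unwounded skin was also present, with Hoxc8 at 3.34 (523 UMIs against 4) and Hoxc6 at 2.56. Papillary genes, which mark fibroblasts near the epidermis, were lower in the dorsal wound, with Rspo1 at -2.58. Cluster 29, led by Saa3, Cxcl5, Tnc and others, held 95.7% of fibroblast-like cells in the dorsal and 10.4% in the facial wound. Immune-like cells were 74.7% against 12.1% of all cells, and S100a8 with S100a9 reached 2631 CPM in fibroblast-like cells of the dorsal wound. Lcn2 and Cxcl2 also led a neutrophil-like cluster of the facial PBS library clustered by itself. Free neutrophil RNA may thus add to their values, which was not tested.

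Inflammatory genes were higher in 14 of 18 members, lower in 2 and between in 2 (median 1.77, percentile 100), with Cxcl2 at 4.96. HOX genes were higher in 13 of 19, lower in 2 and between in 4 (median 0.99; 1.34 with 3 genes at their bound), with Hoxb3 at 1.81 (1 UMI in face, interval of the ratio 4.77 to 12.58). Matrix genes were higher in 14 of 24, lower in 1 and between in 9 (median 0.72, percentile 100), with the proteoglycan Bgn at 1.33 and Thbs1 at 1.21. Matrix proteases and their inhibitors were higher in 12 of 18, lower in 1 and between in 5 (median 0.63): Mmp13 was at 4.605, Mmp3, which leads cluster 29, at 3.29, Mmp9 at 3.04 and Timp1, which inhibits such proteases, at 2.86. Hypoxia and glycolysis genes were higher in 9 of 16 and between in 7 (median 0.79), with Pkm at 1.57 and Slc2a1 at 1.56. Contractile genes were higher in 7 of 15 and between in 8 (median 0.52, percentile 99.9). Papillary genes were lower in 10 of 12 and higher in 2 (median -0.87), with Crabp1 at 1.95. SLIT/ROBO genes were lower in 3 of 7 and between in 4 (median -0.41), with Robo1 at -1.66, Slit2, which leads cluster 7, at -1.57 and Robo2 at -1.10 (38.9 against 88.9 CPM). Eid1 was at -0.42 and Ep300 at 0.17. Other leading genes under the naming rule, which Lcn2 and Cxcl2 did not pass, were the hypoxia regulator Epas1 (4.17), Prg4 (3.95, cluster 29), the antimicrobial lectin Reg3g (3.71) and the glypican Gpc1 (3.45). At the other end were Aldh3a1 (-4.45), Igfbp2 (-4.26), Stmn2 (-3.46), Cyp2f2 (-3.39), Cdh4 (-3.38) and Pcolce2 (-3.36), both of which lead cluster 17, Sectm1a (-3.16) and Ppp1r14a (-3.16).

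Scaling shifted all genes by 0.13; relative to it the medians were 1.64 for inflammatory, 0.86 for HOX, 0.66 for hypoxia, 0.59 for matrix, 0.50 for protease, 0.39 for contractile, -0.998 for papillary and -0.54 for SLIT/ROBO genes. In cluster 7 alone the inflammatory (-0.20), protease (-0.06) and papillary (0.73) medians turned, as did Mmp13 (-0.05), Mmp3 (-0.23), Mmp9 (-0.45), Timp1 (-0.44), Prg4 (-0.69), Reg3g (-0.24), Thbs1 (-0.17), Sectm1a (0.08), Rspo1 (0.42) and Robo2 (0.72), and the matrix median was 0.24. Between the inhibitor wounds of both sites the matrix median was 0.56, while the SLIT/ROBO median (0.34), Slit2 (0.36) and Slc2a1 (-0.09) turned.

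The facial inhibitor wound was compared with the facial PBS wound to describe wounds treated against EP300. Contractile and inflammatory genes were lower in treated fibroblast-like cells: Acta2 had a log2 ratio of -2.35 (interval of the ratio -2.99 to -2.21), Saa3 of -4.01 (14 UMIs against 1981) and Ccl2 of -2.28. Most collagen and other matrix genes lay between, although Tnc (-1.37) and Cthrc1 (-1.16), which lead cluster 29, and Col12a1 (-1.07) and Postn (-0.92) were lower. The WNT transcription factor Lef1, a papillary gene, was at 0.75. Immune-like cells were 5.70% against 12.1% of all cells, and cluster 29 held 4.26% against 10.4% of fibroblast-like cells.

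Contractile genes were lower in 9 of 14 members and between in 5 (median -0.77, percentile 0.0), with Tpm2 at -1.89, Tagln at -1.59 and Lrrc15 at -1.51. Inflammatory genes were lower in 10 of 18 and between in 8 (median -0.69, percentile 0.0), with Cxcl1 at -1.58 and Ccl7 at -1.40. Matrix genes were lower in 4 of 24, higher in 2 and between in 18 (median -0.23, percentile 91.3). WNT genes were higher in 2 of 17, lower in 2 and between in 13 (median 0.30), with Wnt11 at 0.69 and Sfrp2, which leads cluster 29, at -0.78. Papillary genes, 3 of which are also in the WNT list, were higher in 1 of 12 and between in 11 (median 0.23). Reticular and adventitial genes were lower in 4 of 13 and between in 9 (median -0.34, percentile 42.8). Integrin and focal adhesion genes were lower in 1 of 17 and between in 16 (median -0.34, percentile 6.79). EP300 and its partners had 1 of 13 members lower and 12 between (median -0.17, percentile 75.2), with Ep300 itself at -0.14. The lower member was Eid1 (-0.63, 213 against 331 CPM), which lay within 1.5-fold relative to the shift of scaling given below. All 7 SLIT/ROBO genes lay between (median -0.43, percentile 11.1), with Slit2, which leads cluster 7, at -0.50, Slit3 at -0.56 and Robo2 at -0.19 (interval of the ratio -0.42 to 0.02). Among genes that passed the naming rule, which Saa3, Acta2 and Tpm2 did not here, the highest were Cul9 (1.73), the corneal proteoglycan Kera (1.43), Arfgef3 (1.23), Col4a5 (1.11), Coch (1.03), Slc30a5 (1.02), Mamdc2 (0.93) and Cib3 (0.86). Lowest of these beside Ccl2 were Prg4, which leads cluster 29 (-2.21, 5 UMIs against 327), Galnt15 (-1.98), Yae1d1 (-1.89), the retinol carrier Rbp4 (-1.75), Igfbp3 (-1.74), Ifi205 (-1.72) and Mgst3 (-1.69). Scaling shifted all genes by -0.25; relative to it the medians were -0.52 for contractile, -0.44 for inflammatory, 0.02 for matrix, 0.55 for WNT, 0.48 for papillary, -0.09 for reticular, -0.09 for integrin, 0.08 for EP300 and -0.18 for SLIT/ROBO genes. The papillary median was -0.13 with thinned cells and Coch was at -0.77 with more doublets removed. In that doublet setting the cluster led by Coch stayed unnamed, so its cells were left out. In cluster 7 alone Col4a5 (-0.37), Cib3 (-0.10) and Sfrp2 (0.37) turned. The matrix median was -0.11 with more doublets removed.

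The same treatment was compared in dorsal wounds. Inflammatory genes were lower with the inhibitor here too: Saa3 had a log2 ratio of -3.46, Cxcl5 of -3.06, both leading genes of cluster 29, and Cxcl2, a neutrophil chemokine, of -4.85 (16.3 against 611 CPM). Cxcl2 also led a neutrophil-like cluster of the dorsal PBS library clustered by itself. S100a8 with S100a9 stood at 86.5 CPM in fibroblast-like cells with the inhibitor and 2631 with PBS. Free neutrophil RNA may thus add to the Cxcl2 value, which was not tested for single genes. Acta2 was at -1.91. Of genes of reticular and adventitial fibroblasts 7 of 14 were higher, with Pi16, a marker of adventitial progenitors, at 1.72 and Cd34 at 1.21, as were genes that lead cluster 17, Pcolce2 (3.22) and Cdh4 (2.75). Cluster 29 held 38.2% of fibroblast-like cells with the inhibitor and 95.7% with PBS, and cluster 17 held 22.1% against 0.210%. Neutrophil-like cells were 6.52% against 30.5% of all RNA cells but 14.4% against 13.6% of ATAC nuclei. With more doublets removed, unnamed clusters with the hair keratins Krt73, Krt35 or Krt33a among their leading genes held 55, 38 and 25 inhibitor cells. They held 26, 13 and 5 cells of the larger PBS library. The skin cells sampled thus differed between these libraries, which cannot be told apart from the treatment.

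Inflammatory genes were lower in 11 of 18 members, higher in 2 and between in 5 (median -0.73, percentile 0.0), with Lcn2 at -2.58. Hypoxia and glycolysis genes were lower in 10 of 16 and between in 6 (median -0.66), with Slc2a1 at -1.47 and Pkm at -1.33. Cell cycle genes were lower in 9 of 17 and between in 8 (median -0.62), with the mitotic kinase Cdk1 at -1.22 and Top2a at -0.99. Contractile genes were lower in 8 of 15 and between in 7 (median -0.59), with Actn1 at -1.17. Matrix genes were lower in 6 of 24, higher in 2 and between in 16 (median -0.32, percentile 12.5), with Tnc, which leads cluster 29, at -1.78, Col12a1 at -1.45 and the collagen crosslinker Lox at -1.26. Reticular and adventitial genes were higher in 7 of 14, lower in 1 and between in 6 (median 0.56, percentile 100), with Ly6c1 at 1.22 and Dpp4 at 1.18. SLIT/ROBO genes were higher in 3 of 7 and between in 4 (median 0.34, percentile 99.9): Slit2, which leads cluster 7, was at 1.43, Robo1 at 1.14 and Robo2 at 0.78 (70.4 against 38.9 CPM; interval of the ratio 0.67 to 1.05). Papillary genes were higher in 3 of 11, lower in 1 and between in 7 (median 0.30), and adipogenic genes higher in 3 of 9, lower in 1 and between in 5 (median 0.14), with the lipase Lpl at 1.85. Other axon guidance genes were higher in 4 of 17, lower in 4 and between in 9 (median -0.25, percentile 14.0). EP300 and its partners all lay between (13 of 13, median -0.05), with Ep300 at -0.22 and Eid1 at -0.01. Among genes that passed the naming rule, which Cxcl2 and Lcn2 did not, the highest beside those named were Igfbp2 (3.30), Adamts18 (3.07), Stmn2 (2.97), Aldh3a1 (2.77), the WNT antagonist Dkk2 (2.75) and Ppp1r14a (2.46). Lowest of these, after Saa3 and Cxcl5, were Reg3g (-2.81), Reg1 (-2.52), Timp1 (-2.49), Serpina3g (-2.27), Crabp2 (-2.10) and Mmp13 (-2.10).

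Scaling shifted all genes by -0.20; relative to it the medians were -0.53 for inflammatory, -0.46 for hypoxia, -0.42 for cell cycle, -0.39 for contractile, -0.12 for matrix, 0.76 for reticular, 0.54 for SLIT/ROBO, 0.50 for papillary, 0.34 for adipogenic, -0.05 for axon guidance and 0.15 for EP300 genes. In cluster 7 alone the inflammatory (0.58), cell cycle (0.37) and papillary (-0.73) medians turned, as did Igfbp2 (-0.03), Stmn2 (-1.10), Cdh4 (-0.23), Timp1 (0.01), Dpp4 (-0.18), Cdk1 (0.62) and Robo2 (-0.56); in cluster 29 alone the inflammatory median was -0.36, and the SLIT/ROBO median (-0.07), Adamts18 (-0.16), Lpl (-1.09) and Robo2 (-0.21) turned. With each library clustered by itself the papillary (-0.26) and adipogenic (-0.17) medians, Adamts18 (-0.62), Lpl (-0.68) and Robo2 (-0.31) turned, and the matrix median was -0.20. In that setting 83 cells of the inhibitor library, with 10 fibroblast markers and led by Adamts18, Gpc3 and Lpl among others, stayed unnamed. So did 85 cells led by Coch. Cells high in Adamts18 and Lpl were thus left out by construction.

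The inhibitor ratios of face and dorsum were set side by side, without a test because each group is 1 library. The face minus dorsum difference of list medians, taken over members measured at both sites, was 0.09 for matrix and -0.15 for contractile genes (0.12 with each library clustered by itself). Over all members measured at each site, 14 in face and 15 in dorsum, contractile medians were below 0 at both (-0.77 and -0.59), and inflammatory medians likewise (-0.69 and -0.73). The matrix difference ran from 0.02 with libraries clustered alone to 0.21 with more doublets removed.

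**Figure D2:**
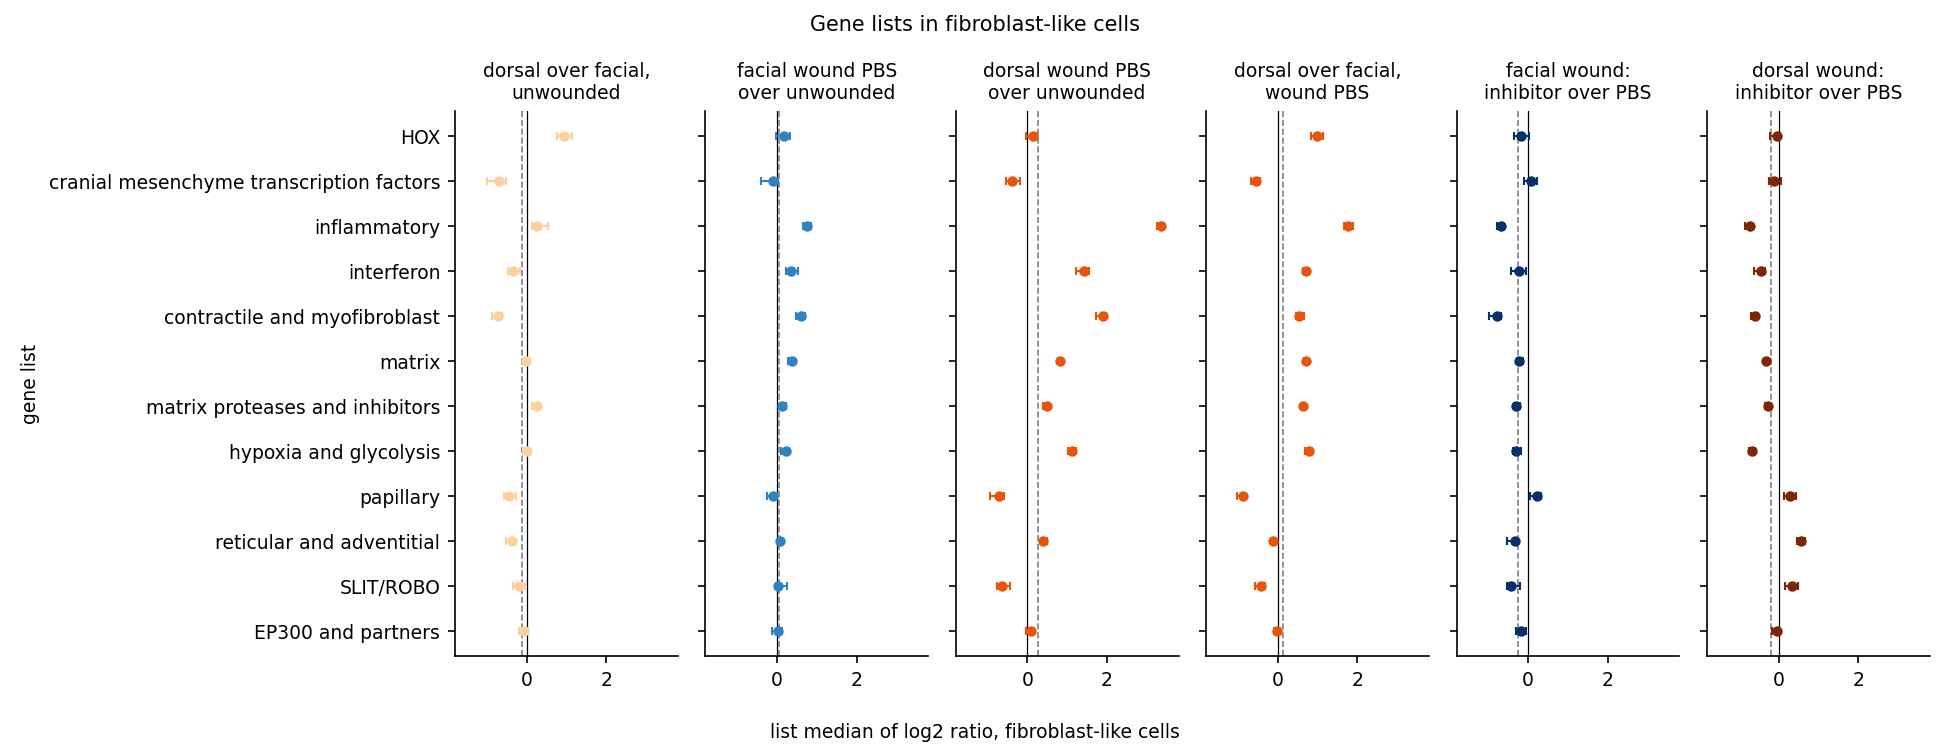
Median log2 ratio of 12 gene lists in fibroblast-like cells for each of the 6 contrasts (x axis, log2 units); points are list medians, lines 95% intervals of counting error, and the dashed line the shift of all genes by scaling. Inflammatory genes stand at 3.35 in the dorsal PBS wound over unwounded dorsum and at -0.69 and -0.73 in the inhibitor contrasts.

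Open chromatin was compared in the same 6 contrasts to relate the transcripts to regulatory regions. The peak sets of wounds with and without the inhibitor overlapped widely: 81.2% of the 85343 peaks of the facial inhibitor wound overlapped a peak of the facial PBS wound, and 83.8% of the 127541 peaks of the dorsal inhibitor wound one of the dorsal PBS wound. Between sites or states overlap depended on the direction, with 46.8% of the 75079 peaks of unwounded dorsum found in unwounded face, 43.7% of the 84068 peaks of the facial PBS wound found in unwounded face, and 42.3% and 48.2% of the 129980 peaks of the dorsal PBS wound found in unwounded dorsum and the facial PBS wound. In the other direction, which for these 4 pairs runs from the smaller set to the larger, the shares were 75.9%, 79.2%, 73.0% and 74.3%. The pairs with and without the inhibitor, whose sets are near in size, had 82.6% in face and 82.3% in dorsum in the other direction. These sets covered 41.8 Mb in unwounded face, 70.5 and 72.8 Mb in the facial wounds, 64.1 Mb in unwounded dorsum and 111 and 109 Mb in the dorsal wounds, and overlap depends on that length and on depth. Among the 40000 strongest peaks of each library the 6 shares given first were 89.6%, 91.4%, 63.9%, 62.2%, 60.0% and 62.8%. A peak at Hoxc8 was called only in the dorsal wound libraries, which have the largest peak sets. It lay on chromosome 15, in coordinates counted from 1 on a build the files do not name. With PBS it ran from 102990174 to 102991009 (310 insertions in fibroblast-like nuclei) and with the inhibitor from 102990150 to 102991086 (508 insertions). None was called in unwounded dorsum, whose fibroblast-like cells had Hoxc8 transcripts, so the call may depend on depth and set size.

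Fibroblast-like nuclei numbered 477, 442, 1006, 1019, 601 and 979 in the order of the groups. Those of unwounded dorsum came from a cluster named on 3 markers, against 7 to 10 markers for fibroblast-like clusters of the other libraries. Clusters of 595 and 355 nuclei there, with fibroblast as best class, stayed unnamed. The contrasts with unwounded dorsum below thus rest on a weaker class. HOX genes were more open in dorsal nuclei, with a median log2 ratio of 0.37 over 11 genes in unwounded skin (percentile 100) and 0.47 over 28 genes in PBS wounds (percentile 100), and cranial regulators were less open in unwounded dorsum (-0.66 over 11 genes). In the inhibitor contrasts all 21 lists had accessibility medians from -0.10 to 0.10. Motif counts were summed over each library's own peak set, and these sets differed in size. No motif share was taken over regions common to a pair, so the sets alone may move the motif ratios below. Motifs of AP-1, the FOS and JUN factors, took a larger share in the dorsal PBS wound than in unwounded dorsum (log2 ratio 0.25) and than in the facial PBS wound (0.25). NF-kB motifs, which serve inflammatory signalling, had 0.37 and 0.26 in these contrasts, and RUNX motifs 0.20 and 0.18. Motifs of SRF and MEF2, regulators of contractile genes, had -0.58 in unwounded dorsum over face and -0.51 in the facial PBS wound over unwounded face. Both ratios rest on unwounded face, where the share was 0.352%, against 0.221% to 0.263% in the other libraries. CTCF motifs had 0.24, 0.64 and 0.33 in the first 3 contrasts, and their share was lowest in unwounded face, at 0.341%. AP-1 stood at 0.11 in unwounded dorsum over face and at 0.10 in the facial PBS wound. In the inhibitor contrasts AP-1 stood at 0.06 in face and 0.01 in dorsum. CEBP motifs were lower in the dorsal inhibitor contrast (-0.15), and the other families shown lay from -0.10 to 0.10 in each. Clustering of nuclei from another random start gave 1760 fibroblast-like nuclei in unwounded dorsum in place of 1019, with AP-1 ratios of 0.07 over face and 0.28 in the dorsal PBS wound; over all nuclei SRF and MEF2 motifs were at 0.10 in the dorsal over facial wound contrast in place of -0.17.

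**Figure D3:**
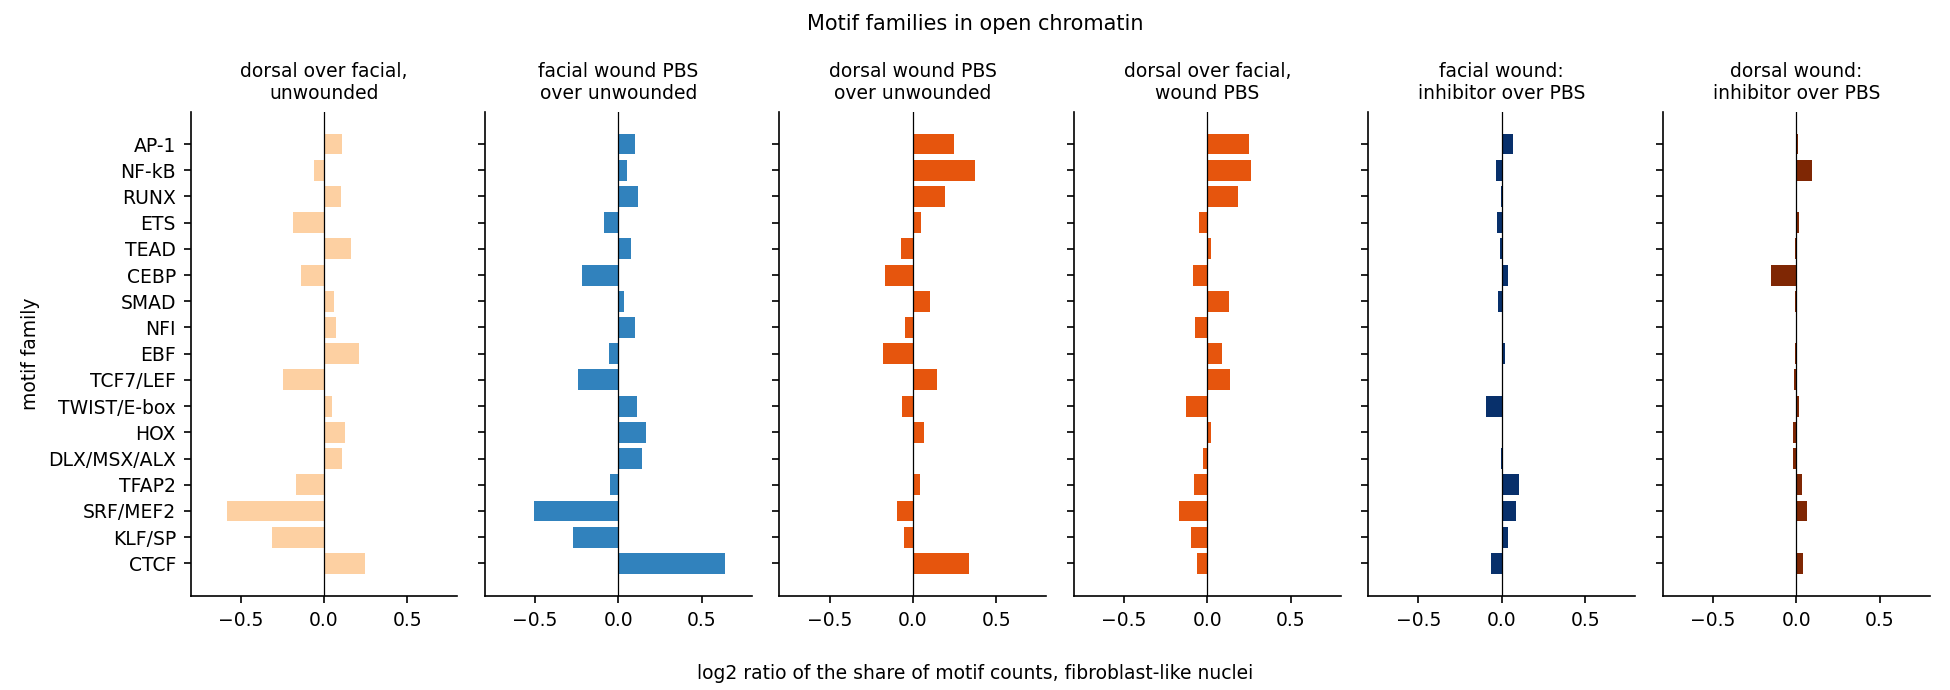
Log2 ratio of the share of motif counts in fibroblast-like nuclei (x axis) for motif families in 6 contrasts; each bar compares a pair of libraries. AP-1 reaches 0.25 and NF-kB 0.37 in the dorsal PBS wound over unwounded dorsum. Motif counts were summed over each library's own peaks.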

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

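The tests of the neutrophil share in the ATAC nuclei and of chance sharing of barcodes were chosen only after the result was seen.

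A difference between sites singled out a pair of lists, whose medians under the inhibitor lay on opposite sides of 0 in face and dorsum and at 0.2 or more from it in both. Nearer to 0, the adipogenic (-0.28 in face, 0.14 in dorsum), trunk dermis (-0.22, 0.07), YAP/TEAD (-0.25, 0.02), immediate early (-0.06, 0.13) and cranial (0.08, -0.11) medians also lay on opposite sides. For reticular and adventitial genes, such as Pi16 and Cd34, the face minus dorsum difference was -0.90 (median -0.34 over 13 measured members in face, 0.56 over 14 in dorsum). For SLIT/ROBO genes it was -0.76 (-0.43 in face, at percentile 11.1 of random lists, and 0.34 in dorsum). The dorsal SLIT/ROBO median turned to -0.07 in cells of cluster 29 alone, so the opposite direction of this list does not hold in every setting. Relative to the shift of scaling the facial medians were -0.09 and -0.18 and the dorsal ones 0.76 and 0.54. The difference was not tested, because each group is 1 library.

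Signal was also found in data outside the comparisons. UMIs assigned to human genes made up 0.310% in unwounded face, 0.258% in the facial PBS wound, 0.589% in the facial inhibitor wound, 0.198% in unwounded dorsum, 0.149% in the dorsal PBS wound and 0.175% in the dorsal inhibitor wound. No explanation of these UMIs was tested.

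Barcodes occurred in more than 1 ATAC library: 488 in unwounded face and the facial inhibitor wound, 419 in both facial wounds, 251 in the facial PBS wound and unwounded dorsum, 374 in the facial inhibitor wound and unwounded dorsum, and 66 in both dorsal wounds. The chance number was set from the sharing seen between the dorsal wound libraries and the libraries outside the dorsal wounds. The first of these numbers is 27.9 times the chance number (25.4 to 30.4), which argues against chance sharing for that pair. Unwounded face shared 1.02 times the chance number with the facial PBS wound and 1.09 times with unwounded dorsum. Regions open in the weaker nucleus were open in its partner 2.48 times as often as in another nucleus of like depth and cluster (2.38 to 2.54; 78.9% against 30.8%, 1432 pairs), so fragments of 1 nucleus counted in a pair of libraries are a candidate explanation. No biological explanation was tested. Leaving these barcodes and nuclei with low counts out removed 360 of 1006 fibroblast-like nuclei of the facial inhibitor wound, with 0.847% of their insertions.

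Neutrophil-like cells were fewer in the dorsal inhibitor wound than in the dorsal PBS wound by RNA, at 6.52% against 30.5%, a ratio of 4.68 (4.05 to 5.52). The share of unfiltered barcodes with S100a8 and S100a9 at 2% or more of UMIs was 7.36 times as high with PBS (6.42 to 8.55). The filter removed 58 of 186 such barcodes with the inhibitor and 174 of 5175 with PBS. As the gap was present before filtering, this argues against removal of neutrophils by the cell filter as the cause of the difference. In ATAC nuclei the ratio was 0.940 (0.842 to 1.04; 13.6% against 14.4%), which argues against a treatment difference in neutrophil share that both assays sample. A difference in how cells and nuclei were prepared, or between animals, stays open and was not tested.

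Inflammatory genes had a median of -0.73 in fibroblast-like cells of the dorsal inhibitor wound over the dorsal PBS wound. Free RNA was estimated at 25.6% of these cells' UMIs with PBS and 3.06% with the inhibitor by S100a8 and S100a9 (2631 and 86.5 CPM). The estimate took the profile of barcodes under 300 genes as free RNA. It also took all S100a8 and S100a9 in these cells as free, although doublets left in would add to them. With the estimated free RNA taken off the median was -0.70 (-0.83 to -0.65). Under these assumptions this argues against free RNA from immune cells as the whole cause. Within cluster 29 alone the list median was -0.36 (-0.47 to -0.24), between the limits set for and against a different mix of clusters. This mix and a difference within cells therefore cannot be told apart. In cluster 7 alone, of which the PBS wound held 59 cells, the median turned to 0.58, so a drop in every cluster is not shown. A treatment effect of the inhibitor stays open, as does a difference between libraries.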

How the results depend on the processing

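The tests with doublet scores removed at a fixed rate, with cluster 7 or 29 alone, with inhibitor wounds in place of PBS wounds, without shared or low-count barcodes and with another random start were chosen only after the result was seen. No paired analysis was possible because each group is 1 library.

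Over the alternatives, 787 gene values stayed within their counting interval, 1208 moved beyond it and 45 turned direction. For list medians these numbers were 358, 198 and 28, for face minus dorsum differences 51, 18 and 1, and for motif families 271, 268 and 1. Counts of list members stayed within 1.5 times in 820 comparisons and moved in 238. Shares of cells stayed in 207 and moved in 117. All 24 shares of peaks moved. These numbers cover the results the text gives, whose lists and list members were picked after reversals had been seen. Only results called as different could be counted as turned: 194 of the 211 gene ratios given and 254 of the 369 left out. Of these called ratios 41 turned under at least 1 alternative among those given and 83 among those left out, so the choice favoured ratios that hold. For called list medians the numbers were 21 of 42 given and 6 of 15 left out, and for face minus dorsum differences, called or not, 1 of 7 and 6 of 14. Except where construction is stated, the cause was not tested.

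With a filter of 500 or more genes and 10% or fewer mitochondrial UMIs, the cell cycle list (-0.087) turned in the facial PBS wound. Fibroblast-like shares were 11.1% in unwounded face, 26.7% in the facial PBS wound, 12.5% in the facial inhibitor wound, 20.2% in unwounded dorsum, 9.25% in the dorsal PBS wound and 21.7% in the dorsal inhibitor wound. With called doublets kept, the cell cycle list (-0.16) turned in the facial PBS wound. Beyond its interval, the matrix median moved to 0.65 in the dorsal over facial wound and -0.26 in the dorsal inhibitor contrast. With each library clustered by itself, the cell cycle list (-0.45) turned in the facial PBS wound. The papillary list (-0.26), the adipogenic list (-0.17), Adamts18 (-0.62), Robo2 (-0.31) and Lpl (-0.68) turned in the dorsal inhibitor contrast. There 83 cells led by Adamts18 and Lpl among others, with 10 fibroblast markers, stayed unnamed and were left out by construction. The face minus dorsum difference of the contractile and myofibroblast list (0.12) turned. Further, the matrix median moved to 0.75 in the dorsal PBS wound, 0.63 in the dorsal over facial wound and -0.20 in the dorsal inhibitor contrast. Fibroblast-like shares were 20.5% in the facial PBS wound, 14.9% in unwounded dorsum, 9.12% in the dorsal PBS wound and 12.3% in the dorsal inhibitor wound. The face minus dorsum difference of the matrix list (0.018) moved. With each cell weighing the same, the cell cycle list (-0.25) turned in the facial PBS wound. The matrix median moved to 0.14 in unwounded dorsum over face, 0.87 in the dorsal PBS wound and -0.37 in the dorsal inhibitor contrast. The face minus dorsum difference of the matrix list (0.20) moved. With cells thinned to 1000 UMIs, the trunk dermis transcription factors list (0.42) turned in unwounded dorsum over face. The papillary list (-0.13) turned in the facial inhibitor contrast. Beyond its interval, the matrix median moved to 0.19 in unwounded dorsum over face, 0.87 in the dorsal PBS wound and -0.40 in the dorsal inhibitor contrast. The face minus dorsum difference of the matrix list (0.20) moved. With size factors by the median of ratios, the matrix median moved to 0.091 in unwounded dorsum over face, 0.54 in the dorsal PBS wound, 0.59 in the dorsal over facial wound, 0.021 in the facial inhibitor contrast and -0.12 in the dorsal inhibitor contrast.

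With the highest doublet scores removed at a fixed rate, Acta2 (0.19) turned in unwounded dorsum over face. Coch (-0.77) turned in the facial inhibitor contrast. A cluster of 796 cells led by Coch, Col11a1 and Tnmd, with 6 fibroblast markers, stayed unnamed in this setting and was left out by construction. The matrix median moved to -0.095 in unwounded dorsum over face, 0.76 in the dorsal PBS wound and -0.11 in the facial inhibitor contrast. Fibroblast-like shares were 5.63% in unwounded face, 17.1% in the facial PBS wound, 6.48% in the facial inhibitor wound, 13.1% in unwounded dorsum, 7.66% in the dorsal PBS wound and 15.6% in the dorsal inhibitor wound. The face minus dorsum difference of the matrix list (0.21) moved. In cells of cluster 7 alone, the matrix proteases and inhibitors list (-0.28), the papillary list (0.027), Pi15 (-0.38) and Postn (0.14) turned in unwounded dorsum over face. The cell cycle list (-0.0079) turned in the facial PBS wound. The TGF-beta pathway list (-0.083), the papillary list (0.73), the SLIT/ROBO list (0.19), the inflammatory list (-0.66), the cell cycle list (-0.88), Scara5 (0.58), Robo2 (0.76), Cthrc1 (-0.011), Ltbp1 (0.51) and Rspo1 (0.087) turned in the dorsal PBS wound. The matrix proteases and inhibitors list (-0.063), the papillary list (0.73), the inflammatory list (-0.20), Mmp13 (-0.052), Prg4 (-0.69), Reg3g (-0.24), Sectm1a (0.083), Robo2 (0.72), Thbs1 (-0.17), Mmp3 (-0.23), Mmp9 (-0.45), Timp1 (-0.44) and Rspo1 (0.42) turned in the dorsal over facial wound. The papillary list (-0.73), the inflammatory list (0.58), the cell cycle list (0.37), Igfbp2 (-0.027), Stmn2 (-1.10), Cdh4 (-0.23), Timp1 (0.0061), Robo2 (-0.56), Dpp4 (-0.18) and Cdk1 (0.62) turned in the dorsal inhibitor contrast. Col4a5 (-0.37), Cib3 (-0.10) and Sfrp2 (0.37) turned in the facial inhibitor contrast. Beyond its interval, the matrix median moved to 0.73 in the dorsal PBS wound, 0.24 in the dorsal over facial wound and -0.26 in the dorsal inhibitor contrast. In cells of cluster 29 alone, the SLIT/ROBO list (-0.069), Adamts18 (-0.16), Robo2 (-0.21) and Lpl (-1.09) turned in the dorsal inhibitor contrast. Further, the matrix median moved to -0.25 in the dorsal inhibitor contrast. With inhibitor wounds in place of PBS wounds, the contractile and myofibroblast list (-0.36), the inflammatory list (-0.21), the cell cycle list (-0.0026), Ccl2 (-0.51), Myoc (0.098), Tnc (-0.16), Lrrc15 (-0.43), Tpm2 (-0.83), Acta2 (-1.60) and Cxcl1 (-0.064) turned in the facial PBS wound. The SLIT/ROBO list (0.016) and Klf4 (0.033) turned in the dorsal PBS wound. The SLIT/ROBO list (0.34), Slit2 (0.36) and Slc2a1 (-0.093) turned in the dorsal over facial wound. The matrix median moved to 0.17 in the facial PBS wound, 0.60 in the dorsal PBS wound and 0.56 in the dorsal over facial wound.

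Over all nuclei, the SRF/MEF2 motif (0.097) turned in the dorsal over facial wound. The AP-1 motif ratios moved to 0.075 in unwounded dorsum over face, -0.0042 in the dorsal inhibitor contrast, 0.19 in the dorsal PBS wound, 0.14 in the dorsal over facial wound, 0.053 in the facial inhibitor contrast and 0.12 in the facial PBS wound. With each nucleus weighing the same, the AP-1 motif ratios moved to 0.12 in unwounded dorsum over face, 0.017 in the dorsal inhibitor contrast, 0.23 in the dorsal PBS wound, 0.30 in the dorsal over facial wound, 0.10 in the facial inhibitor contrast and 0.046 in the facial PBS wound. With motif counts per insertion in peaks, the AP-1 motif ratios moved to 0.083 in unwounded dorsum over face, 0.0028 in the dorsal inhibitor contrast, 0.28 in the dorsal PBS wound, 0.29 in the dorsal over facial wound, 0.10 in the facial inhibitor contrast and 0.081 in the facial PBS wound. With nuclei clustered from another random start, the AP-1 motif ratios moved to 0.070 in unwounded dorsum over face and 0.28 in the dorsal PBS wound. With a reciprocal overlap of 50%, shares of peaks found were 45.8% for unwounded dorsum in unwounded face, 42.6% for facial PBS wound in unwounded face, 41.4% for dorsal PBS wound in unwounded dorsum, 47.2% for dorsal PBS wound in facial PBS wound, 80.8% for facial inhibitor wound in facial PBS wound and 83.4% for dorsal inhibitor wound in dorsal PBS wound. With the 40000 peaks of highest counts per library, shares of peaks found were 63.9% for unwounded dorsum in unwounded face, 62.2% for facial PBS wound in unwounded face, 60.0% for dorsal PBS wound in unwounded dorsum, 62.8% for dorsal PBS wound in facial PBS wound, 89.6% for facial inhibitor wound in facial PBS wound and 91.4% for dorsal inhibitor wound in dorsal PBS wound.

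Depth limits the thinned setting, which leaves out cells with fewer UMIs by construction, and cluster 7 of the dorsal PBS wound, which holds 59 cells. Without shared and low-count barcodes, the AP-1 motif ratios stayed within their counting intervals.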

Other observations

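No tests are reported in this part; the genes and classes below were picked after their values were seen.

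Other cell classes differed between the dorsal inhibitor wound and the dorsal PBS wound as well. In monocyte- and macrophage-like cells (265 against 3151 cells), Cd209d had a log2 ratio of 3.95, Mgl2 of 3.81, Cbr2 of 3.01, Cd163 of 2.93 and Clec10a of 2.92. Arg1 was at -3.51, Cxcl3 at -3.18, Nos2 at -3.15, Cxcl9 at -2.38 and Inhba at -2.25. The class is a mix of 3 clusters: cluster 14, led by Ccl8 and Pf4, held 141 of the cells with the inhibitor and 776 with PBS, cluster 15, led by Mmp12, Arg1 and Cxcl3, 17 and 729, and cluster 22, led by Chil3, 107 and 1646. These ratios were not taken within clusters, so the mix and a difference within cells are not separated. In the dorsal PBS wound over unwounded dorsum (86 cells) Cd209d was at -7.01, Mgl2 at -6.21 and Cd163 at -4.71. For the dorsal inhibitor wound over the dorsal PBS wound, the hypoxia and glycolysis median of this class was -1.06, with 14 of 16 members lower and 0 higher.

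Inflammatory medians in the dorsal inhibitor wound over the dorsal PBS wound were -1.28 in blood endothelial-like, -1.74 in epithelial-like and -1.19 in mural-like cells. They were -2.57 in Schwann-like, -0.75 in dendritic-like and -0.39 in neutrophil-like cells. Free RNA was not measured or taken off in these classes. In fibroblast-like cells it was estimated from S100a8 and S100a9 at 25.6% of UMIs with PBS and 3.06% with the inhibitor. Matrix medians were -1.08 in neutrophil-like, -1.03 in T- and NK-like and -1.54 in dendritic-like cells, classes that make little matrix.

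The share of NFYA motif counts in fibroblast-like nuclei had log2 ratios of 0.59 and 0.86 in PBS wounds over unwounded face and dorsum, and of -0.89 and -1.03 with the inhibitor in face and dorsum. NFYB, which binds in the same complex, stood at -0.02, -0.17, -0.05 and -0.16 in these contrasts, and NFYC at -0.05, -0.27, -0.07 and 0.04. The NFYA share in face and dorsum was 0.0534% and 0.0506% unwounded, 0.0804% and 0.0921% with PBS, and 0.0432% and 0.0450% with the inhibitor. All 4 NFYA ratios use the PBS libraries, so a deviation of these alone would give opposite directions. Motif counts were summed over each library's own peaks.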
